A study of Arabidopsis thaliana with 15 samples.

How the data were processed

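RNA from sorted root protoplasts of Arabidopsis thaliana was measured on Affymetrix ATH1 arrays, 1 array per sample. Roots of 6-day-old seedlings were treated with 10 nM brassinolide (BL, the most active brassinosteroid), and fluorescent cells were isolated by fluorescence-activated sorting. Cells carrying pWOL:GFP, which labels the stele, were collected untreated and after 0.5, 1, 2 and 4 h of BL, with 2 arrays in each of these 5 groups. Cells carrying pAtHB15:YFP, which labels provascular cells, were collected untreated on 3 arrays and after 2 h of BL on 2 arrays. The groups are called WOL and ATHB15 here. Per the labels, biotin-labelled RNA was made with the Affymetrix 2-cycle amplification. The labels name no mock treatment matched in time. The labels name no array batch, and nothing in the sources used here says whether the replicates are separate cultures, so a p may measure only the spread between arrays.

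The deposited values are signal intensity on a linear scale, given in both deposited tables, whose signals were identical on 342150 of 342150 values. On every array the mean without the lowest and highest 2% of probe sets was 250, so the deposited intensity was scaled to a common trimmed mean. Per the file headers, the fuller table also holds a detection p-value for each probe set and array, and, as its other kind of column, a detection call of present, marginal or absent. These headings are those of the Affymetrix MAS5 statistical algorithm, but the software is not given in the sources used here. The detection calls were used for the share of probe sets called present, for a filter and for lower bounds on folds.

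The table holds 22810 probe sets. The 64 Affymetrix control probe sets were left out and 22746 were tested. Signals were analysed as log2(signal + 16). The planned analysis took the deposited values to be log2 values, and the offset of 16 was chosen once they were seen to be linear and to include 1 signal of 0. In the probe annotation used here, 13513 of the tested probe sets match 1 gene, 503 match several, and 8730 have no gene listed and are left unnamed. Gene names come from the same annotation and the reference gene table.

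Differences were fitted in limma 3.58.1 under R 4.3.3, with 1 mean for each of the 7 groups over all 15 arrays and moderated variances (8 residual and 6.34 prior degrees of freedom). All tests are two-sided, p-values were adjusted by the Benjamini-Hochberg method over all probe sets within a comparison, and a probe set was called at an adjusted p under 0.05. The comparisons were each WOL BL time against the WOL control, each BL time against the one before it, any change over the WOL time course (moderated F test), ATHB15 BL against its control, the difference of the 2 h BL change between the lines, and the ATHB15 control against the WOL control. Residual spread is shared by all groups, so a group left with 1 array is assumed to vary like the others. Tests were checked on simulated data with 50 probe sets given a known log2 change of each size, all sizes at once. The changed probe sets were drawn without the dim ones. Noise was independent for each probe set and array, with no deviation shared across an array, so recovery in the real data may be lower. At 2 h in WOL, 8% of changes of 1, 68% of changes of 2 and 92% of changes of 3 were recovered, and in ATHB15 12%, 68% and 96%.

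Named genes follow a rule set before the data were examined: up to 10 rises and 10 falls with the largest log2 change among called probe sets that match 1 gene and whose arrays do not overlap between the groups (for the difference between lines, the call alone). Where fewer than 5 were called in a direction, the 5 with the smallest p are named as not past the threshold. Members of the gene lists may also be named. Where all arrays of the lower group were called absent, only a lower bound on the fold is given, with each absent signal raised to the lowest signal called present on its array if below it, and where both groups were absent no fold is given. Such a limit allows for detection and not for the spread between arrays, so for limits and other sizes a value or range without 1 array is given where leaving it out moves the fold by over 1.5 times. For the difference between lines a bound is given only if a lower signal in the absent group would make the difference larger.

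Before the data were examined, 26 gene lists with 290 genes were fixed, and 37 of these genes have a probe set that the annotation names. Lists were tested with limma's camera at a preset correlation of 0.01 if at least 3 members were measured, which left 6 lists and 60 tests, adjusted together. Camera with an estimated correlation was run beside it, and limma's fry. Coverage of these lists was between 15% and 45.5%, so a list result describes only its measured members. A further 21 families were picked from gene names before any test (210 tests), and 5 lists were chosen after the comparisons were seen (50 tests). Each kind was adjusted separately.

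Alternatives set before the data were examined were the other table, quantile normalization, median centring, filters on dim probe sets, an intensity trend with robust moderation, array weights, omission of probe sets matching several genes, the replicate label as a block, fits on fewer groups, other thresholds and leaving out each array in turn. Offsets of 1 and 64, a filter on detection calls, the GAPDH, UBQ or actin 3' to 5' ratio as a covariate, and the omission of the WOL BL 4 h arrays, or of WOL control B with WOL BL 4 h A, were added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for file handling and figures. For arrays, their number limits the precision. Raw probe intensities were not used here.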

Results

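Transcripts were measured in sorted stele and provascular cells of Arabidopsis roots, with and without brassinolide, on 15 arrays in 7 groups. WOL control, WOL BL 0.5 h, WOL BL 1 h, WOL BL 2 h, WOL BL 4 h and ATHB15 BL 2 h have 2 arrays each, and ATHB15 control has 3. Between 49.5% and 59.6% of probe sets were called present on an array. Across all probe sets, the correlation between 2 arrays of 1 group was 0.898 to 0.962, and its median was 0.938 within a line and 0.870 between the lines. The first principal component held 49.7% of the variance and separated the lines. WOL control B lay at 21.41 on it, between WOL control A at -41.97 and the ATHB15 arrays, whose lowest value was 59.78. WOL control B also had the highest GAPDH 3' to 5' signal ratio of the 15 arrays, 4.66, a sign of RNA quality. The UBQ 3' to 5' ratio was 5.99 to 9.07 in ATHB15 BL 2 h against 4.01 to 4.85 in ATHB15 control. In WOL control it was 5.07 to 7.43, against 2.91 to 4.62 in WOL BL 1 h and 3.79 to 4.90 in WOL BL 2 h. Both WOL controls also had a higher GAPDH ratio, 2.71 to 4.66, than the WOL BL 0.5 h and 1 h arrays, 1.24 to 2.23. Their actin ratio was 28.4 to 48.3, against 17.8 to 26.1 over WOL BL 0.5 h, 1 h and 2 h. The UBQ ratio overlapped at 0.5 h, the GAPDH ratio at 2 h and all of these ratios at 4 h. Where a ratio did not overlap, an effect of BL in WOL cells cannot be told apart from RNA quality that it tracks.

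**Figure D1:**
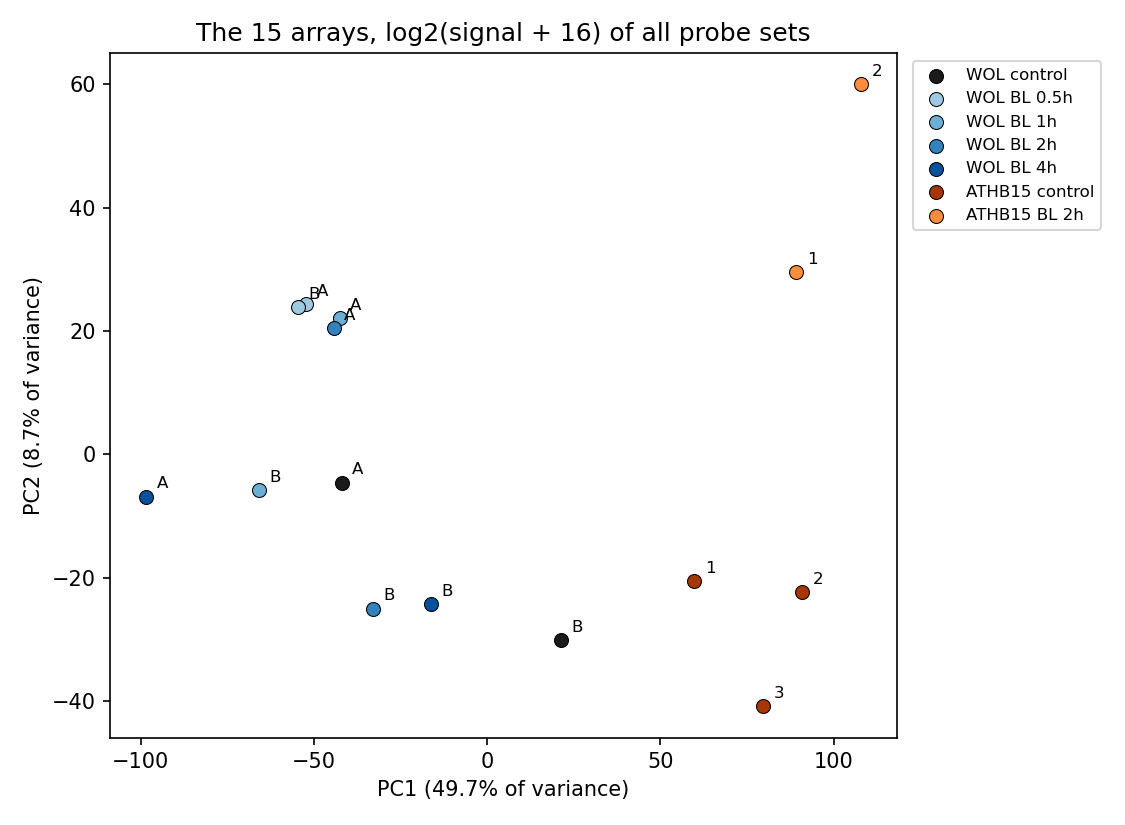
The 15 arrays on the first 2 principal components of log2(signal + 16), with the share of variance on each axis, coloured by group and marked with the replicate. The ATHB15 arrays lie to the right and WOL control B, at 21.41 on the horizontal axis, lies nearest to them among the WOL arrays.

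The WOL time course asks which stele transcripts respond to BL and when. The gene with the smallest p among the rises at 2 h was EXLA2, an expansin-like gene. Its log2 difference from the control was 2.18 ± 0.44 (SE, n = 2 and 2) at 2 h and 2.07 at 4 h, with mean signals of 213 in the control, 1019 at 2 h and 996 at 4 h. IQD16, of the calmodulin-binding IQ-domain family, had a signal at least 4.88-fold lower at 1 h and 5.97-fold lower at 2 h than in the control, limits that were 3.01 and 3.68 without WOL control B and 7.92 and 9.69 without WOL control A. At 1 h the signal was at least 6.27-fold higher for AT2G43610 and 4.60-fold higher for AT1G29020, and the log2 differences were 2.36 for AT1G52060 and 2.02 for AT3G23190. At 0.5 h AT3G43960 differed by 2.18 (1.48 without WOL control B and 2.88 without WOL control A) and AT1G26680, called absent on 1 of 2 control arrays too, had a signal at least 3.44-fold lower, and at 4 h the helicase gene PRH75 differed by -2.04. None of these passed the threshold in limma: the adjusted p was 0.464 for EXLA2 at 2 h and 0.325 for AT1G26680 at 0.5 h.

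No probe set was called by limma at any of the 4 times. At an unadjusted p under 0.05 there were 2057 probe sets at 0.5 h, 1510 at 1 h, 1505 at 2 h and 1903 at 4 h, where 1137 would be expected by chance. The F test over the time course called 0, with 1301 at an unadjusted p under 0.05. Steps between times also gave 0 calls, with 711 at an unadjusted p under 0.05 from 0.5 to 1 h, 542 from 1 to 2 h and 985 from 2 to 4 h. Without WOL BL 4 h B, 21 probe sets were called at 4 h. Median centring moved the median of all genes by 0.10 at 1 h and 0.17 at 2 h.

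Genes of the xyloglucan endotransglucosylase/hydrolase (XTH) family, which remodel cell wall xyloglucan, were higher as a list in BL-treated WOL cells at each time. With 6 of 15 listed genes measured, 5, 5, 4 and 6 members were higher at 0.5, 1, 2 and 4 h, and the median log2 difference was 1.02, 1.11, 1.26 and 0.93. The list's adjusted p was 0.00969 at 0.5 h, 0.0110 at 1 h, 0.00565 at 2 h and 0.0181 at 4 h in limma's camera. None was called with an estimated correlation (adjusted p = 0.556 with an estimated correlation at each time). Over all genes 0 members were called at any time, and adjusted over the list alone 1, 3, 4 and 0 were higher. XTH19 differed by 1.94 at 0.5 h, 2.06 at 1 h and 1.79 at 2 h, XTH18 by 1.51 at 1 h and 1.52 at 2 h, XTH16 by 1.09 at 1 h and 1.03 at 2 h, and XTH21 by 1.50 at 2 h. Without WOL control B XTH19 stood at 0.78, 0.90 and 0.63 and XTH18 at 0.68 and 0.69, and without WOL control A each was larger.

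The XTH calls rested on WOL control B, where the mean log2 value of the list was 7.32, against 8.50 in WOL control A and 8.34 to 9.21 in the BL arrays. Without WOL control B the adjusted p was 0.382, 0.446, 0.370 and 0.618 at the 4 times and the median log2 difference fell to 0.45, 0.63, 0.66 and 0.34, where the p ran from 0.000221 to 0.673 over all alternatives and times. Without WOL control A the median at 0.5 h was 1.58. The call was also lost at 1 h without WOL BL 1 h A (0.250), at 2 h without WOL BL 2 h A (0.235), and at 4 h without WOL BL 4 h A (0.200) or B (0.0659, with a larger median of 1.55). With the GAPDH ratio as a covariate the call was lost at 0.5 h (0.673), 1 h (0.178) and 2 h (0.0819) and kept at 4 h (0.0201). The medians with it were 0.31, 1.05, 1.06 and 0.93. With the UBQ ratio the call at 1 h was lost (0.0539), with a median of 1.29.

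Among the other fixed lists, growth genes known to be induced by brassinosteroids were higher at 1 h, with 3 of 3 measured members higher, a median of 0.86 and an adjusted p of 0.0110 (limma). That call was lost with an estimated correlation in camera (adjusted p = 0.556), without WOL control B and without WOL BL 1 h A. The mean log2 value of the list was 8.09 in WOL control A and 7.04 in WOL control B, against 8.90 and 8.26 in WOL BL 1 h A and B. The rise was thus smaller without WOL control B, and the median was 1.43 without WOL control A. EXPA8, an expansin called absent on 1 of 2 control arrays, differed by 1.50 (0.63 without WOL control B and 2.38 without WOL control A) and was the 1 member higher when adjusted over the list alone; over all genes 0 were. At 2 h, where the list was not called (adjusted p = 0.207, limma camera), EXO differed by 0.92 and was not called (adjusted p = 0.731, limma). Auxin response genes were lower at 2 h than at 1 h, 6 of 6 of those measured, with a median of -0.66 and an adjusted p of 0.0111 (limma), and adjusted p = 0.556 with an estimated correlation; 0 members were called over all genes or adjusted over the list alone. That call was lost without WOL BL 1 h A (0.0586), WOL BL 1 h B (0.0707) or WOL BL 2 h A (0.0969), over a range of 0.00813 to 0.556.

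Expansins went both ways in WOL cells and the list was not called. EXPA15 differed by -1.85 at 2 h and -2.06 at 4 h. EXPA18, called absent on 1 of 2 control arrays, differed by 1.98 at 0.5 h (1.10 without WOL control B and 2.87 without WOL control A), a value that turned to -0.36 with the GAPDH ratio as a covariate. The lists for procambium (3 measured) and ground tissue (4 measured) were not called at any time or step, with smallest adjusted p of 0.246 each. Of lists with under 3 measured members, the receptor gene BRL1 had a signal at least 2.74-fold lower at 2 h, and BBM, a gene of root stem cells called absent on 1 of 2 BL arrays, differed by -2.06 at 4 h (-1.17 without WOL BL 4 h A and -2.95 without WOL BL 4 h B). None of these was called over all genes in limma, except BBM without WOL BL 4 h B (adjusted p = 0.0380).

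**Figure D2:**
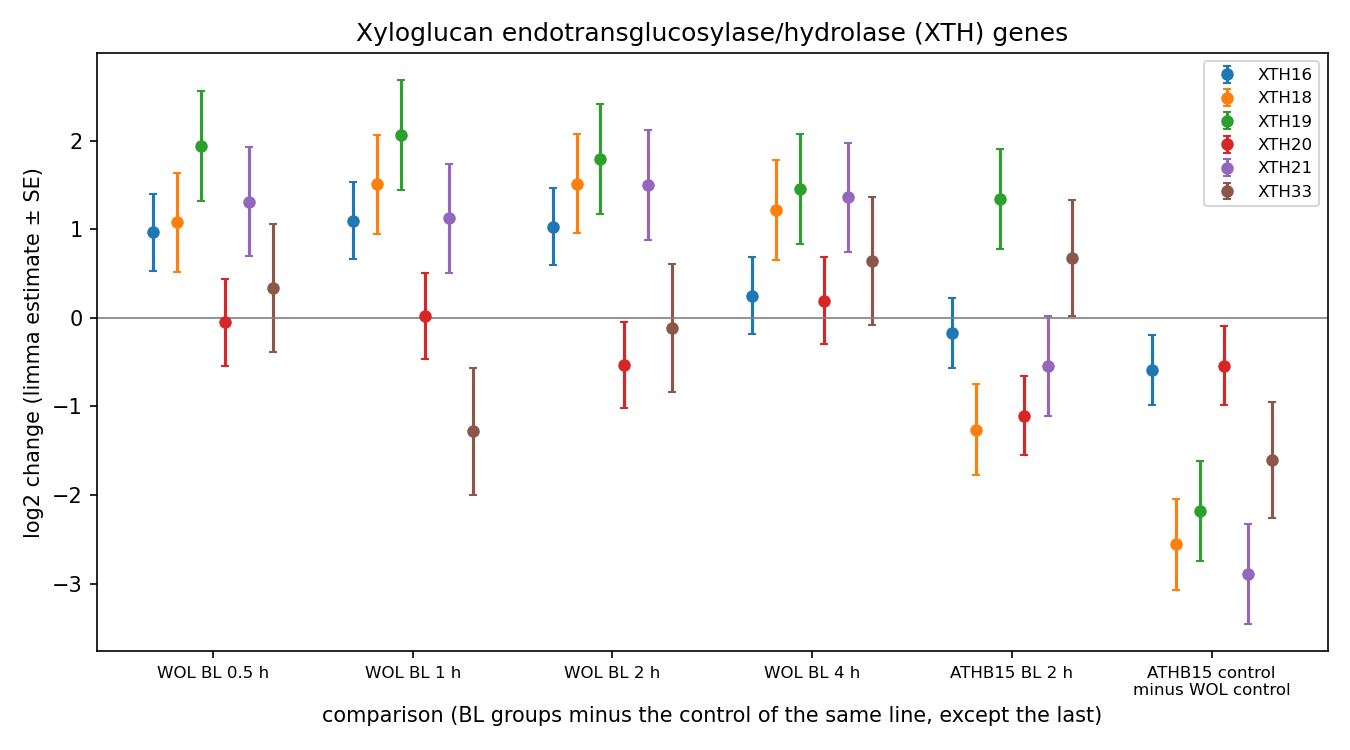
Log2 differences of the 6 measured XTH genes (points, limma estimates with bars of 1 SE) for each BL group against the control of its line, and for the ATHB15 control against the WOL control. XTH19 lies at 2.06 at 1 h in WOL cells, and the 6 genes lie under 0 in the last comparison.

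BL changes in WOL cells correlated across genes between times, with r from 0.570 to 0.717, where the shared control arrays alone gave about 0.50 in simulation. The simulation gave every group the same spread for a probe set. The median SD was 0.322 in WOL control, against 0.196, 0.249 and 0.253 at 0.5, 1 and 2 h and 0.416 at 4 h. A noisier shared control raises r, so the excess over 0.50 does not show a shared BL response. Genes are not independent replicates. The covariance exceeded the simulated value by 0.0622 to 0.102, which is undecided for the same reason. No calls were shared between times or lines, because limma made 0 in WOL.

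In provascular (ATHB15) cells, genes of several kinds differed between 2 h of BL and the untreated control, and the comparison asks which. No mock treatment matched in time is named, so effects of time or handling cannot be told apart from BL. ZW9, a TRAF-like gene, rose by 4.66 ± 0.72 on the log2 scale (SE, n = 2 and 3), from a mean signal of 86.4 to 2061 (adjusted p = 0.00861, limma), and was called absent on 1 of 3 controls. The jacalin lectin gene AT2G25980 rose at least 11.9-fold, and the TRAF-like genes AT3G20370 and AT5G26260 rose at least 8.15-fold and 8.07-fold. NAI2, which builds ER bodies (endoplasmic reticulum stores of defence enzymes), rose at least 6.77-fold. The terpene synthase gene AT1G33750 rose at least 4.88-fold, the peroxidase gene AT3G01190 at least 7.22-fold, the pectin lyase-like gene AT2G43890 at least 6.49-fold and AT1G67330 at least 6.45-fold. Without ATHB15 BL 1 the limit was 12.8 for AT5G26260, 4.71 for AT3G01190 and 3.70 for AT2G43890, without ATHB15 BL 2 it was 5.09, 11.1 and 11.4, and the rise of ZW9 was 5.29 without ATHB15 control 3. AT1G62660, a vacuolar invertase gene called absent on 2 of 3 controls, rose by 2.85 on the log2 scale.

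Among the falls in ATHB15 cells, STZ, a zinc finger repressor of stress responses, fell by 3.24 on the log2 scale, from a mean signal of 1711 to 161. The dirigent gene AT4G11210 fell by 3.28, the lipid-transfer gene AT3G18280 fell by 3.15 and the lipid-transfer gene AT1G73780 fell by 2.95. AT1G79620, a receptor-like kinase gene, fell by 2.72. AT2G01300 fell at least 10.2-fold. The log2 change was -3.77 for AT2G18210, -3.29 for AT1G62480, -2.95 for AT1G72230 and -2.76 for AT3G59370; AT2G18210 and AT3G59370 were called absent on 1 of 2 BL arrays. AT2G18210 stood at -3.18 without ATHB15 BL 1 and -4.35 without ATHB15 BL 2, and AT1G62480 at -2.52 and -4.07. These 20 genes passed the threshold in limma with every BL array beyond every control array.

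Of the fixed lists, auxin response genes had the smallest p in ATHB15 cells: 5 of 6 measured members were lower, with a median of -0.81 and an adjusted p of 0.0924 (limma), not past the threshold. The call was made without ATHB15 control 3 (0.0488), without ATHB15 BL 2 (0.0192) and with the GAPDH ratio (0.0201, with a median of -0.80) or the actin ratio (0.0281) as a covariate, over a range of 0.0192 to 0.556. LBD16, a gene of lateral root initiation, differed by -1.95 and was the 1 member lower when adjusted over the list alone, where 0 were called over all genes. XTH18 stood at -1.26 and XTH19 at 1.34, both called absent on 2 of 3 controls and XTH18 on 1 of 2 BL arrays, and the XTH list was not called (0.715), nor were expansins (0.466), procambium (0.552), ground tissue (0.792) or growth genes (0.967).

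In all, limma called 253 probe sets in ATHB15 cells, 80 higher and 173 lower, with 3113 at an unadjusted p under 0.05. The count was 134, 160 and 67 without ATHB15 control 1, 2 and 3, and 42 and 20 without ATHB15 BL 1 and 2, and in each case the 253 changes kept their sign. Of the 10 named rises, 6, 5 and 4 lost the call without ATHB15 control 1, 2 and 3, and 9 and 8 without ATHB15 BL 1 and 2; of the 10 named falls, 2 and 5 did without ATHB15 BL 1 and 2. AT1G33750, AT1G62480, AT4G11210, AT1G73780 and AT3G59370 kept the call in each of these. With the UBQ ratio as a covariate the count was 1, AT1G33750, and 19 of the 20 named genes lost the call, with each sign kept; with the GAPDH ratio it was 63 and with the actin ratio 96.

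Whether the response to 2 h of BL differs between the lines was tested directly. The log2 change of AT1G62480 was -3.29 in ATHB15 cells and 1.26 in WOL cells, a difference between lines of -4.55 ± 0.62 (SE; adjusted p = 0.0185, limma) that was -3.77 without ATHB15 BL 1 and -5.32 without ATHB15 BL 2. The change was lower in ATHB15 cells by at least 4.56 on the log2 scale for AT2G01300, where the difference was -3.89 without WOL control B and -5.24 without WOL control A, and by at least 3.15 for AT1G78260. It was also lower for EXLA2 (adjusted p = 0.0226), with no size given, because EXLA2 was called absent on both ATHB15 BL arrays and on 2 of 3 ATHB15 controls. The change differed by -3.73 for the lipid-transfer gene AT1G73780, -3.55 for the dirigent gene AT4G11210, -3.03 for the receptor-like kinase gene AT1G79620, and between -3.43 and -3.59 for AT3G59370, AT1G12080 and AT1G72230. In the other direction it differed by 2.99 for the DEAD-box helicase gene AT3G06480, 2.90 for the F-box gene AT3G27150 and 2.84 for AT1G50380. The pectin lyase-like gene AT2G43890 and AT2G41810 were also called higher, with no size given. For both, the ATHB15 controls and the WOL arrays of both groups were called absent, so their change in WOL cells is not measured. STZ differed by -3.86 between the lines, which was not past the threshold (adjusted p = 0.0558, limma). It was called in only 8 of 26 alternatives, among them median centring (0.0293), over a range of 0.0117 to 0.951. The difference was -3.39 without WOL control B and -4.32 without WOL control A.

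**Figure D3:**
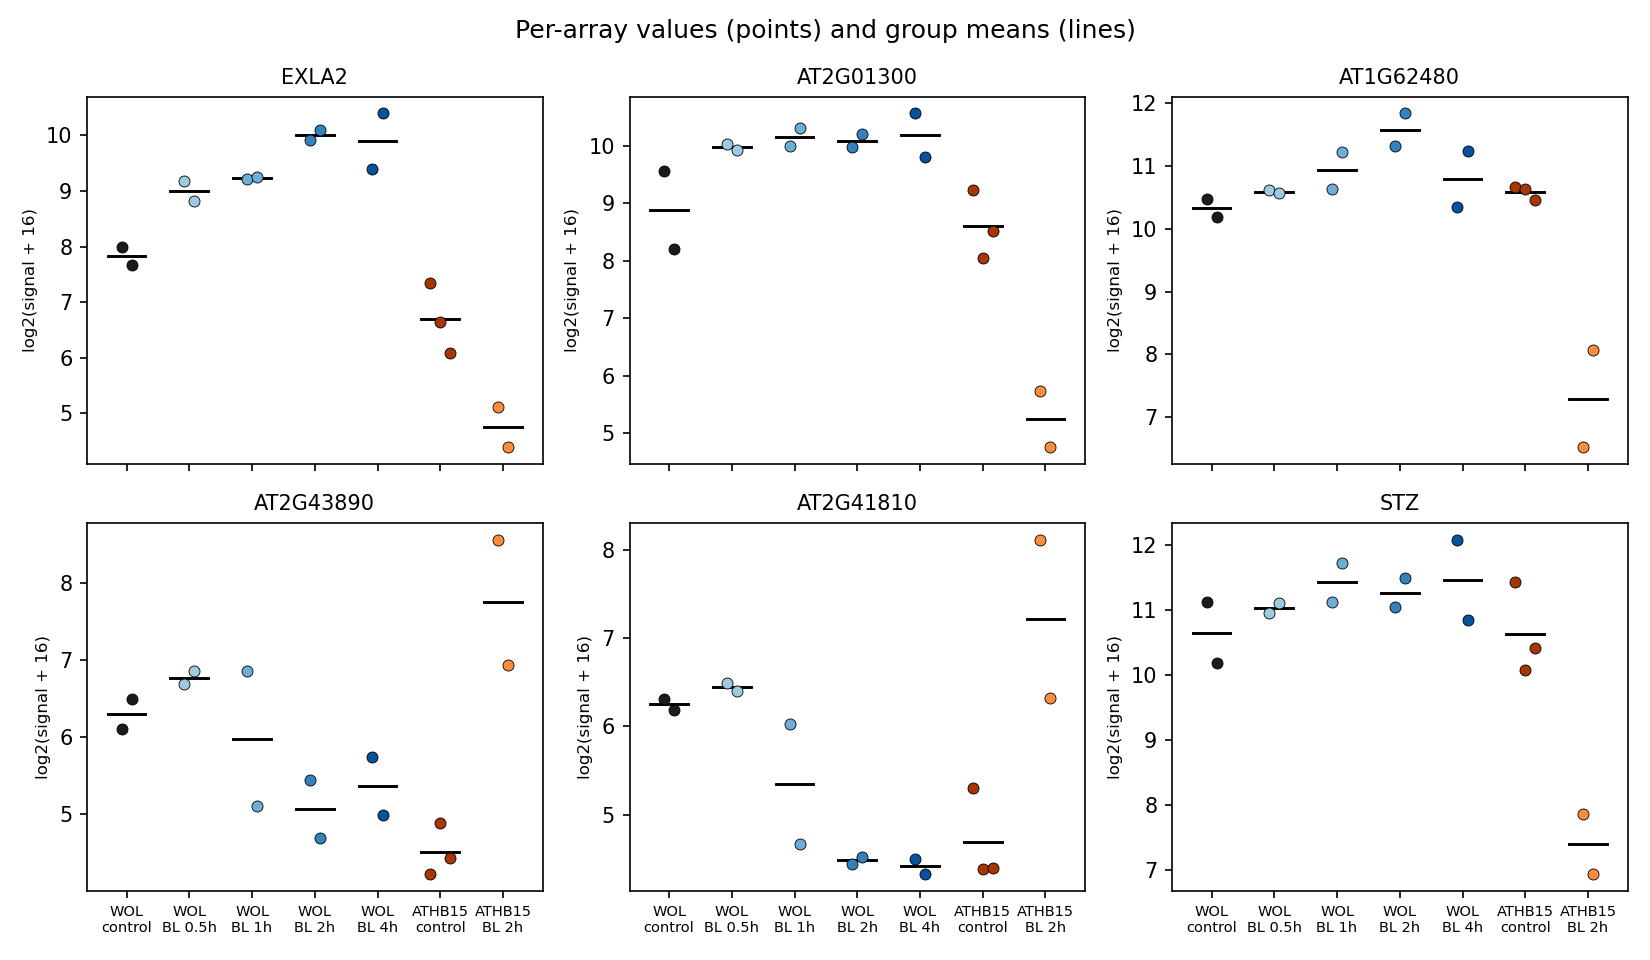
Values of 6 genes on each array (points, log2 of signal + 16) by group, with group means as lines. EXLA2 has group means of 7.83 in WOL control, 10.01 in WOL BL 2 h, 6.69 in ATHB15 control and 4.75 in ATHB15 BL 2 h, where it was called absent.

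Limma called 29 probe sets for this difference, 8 higher and 21 lower, with 2735 at an unadjusted p under 0.05. Of the 29, 28 were also called in ATHB15 cells, whose arrays both tests share. XTH genes were lower as a list, 5 of 6, with a median of -0.88 and an adjusted p of 0.0364 (limma), and adjusted p = 0.556 with an estimated correlation; 0 were called over all genes and 1 was lower adjusted over the list alone, XTH18 at -2.78 (-1.95 without WOL control B and -3.60 without WOL control A), which was called absent on 2 of 3 ATHB15 controls and was called over all genes without WOL control A (0.0477). That list call was lost with quantile normalization (0.0788) and median centring (0.0559), where the median stayed at -0.92 and -0.97, and without WOL control B (0.446, with a median of -0.43), WOL BL 2 h A (0.313), ATHB15 control 1 (0.0882) or ATHB15 BL 1 (0.188), and with the UBQ ratio as a covariate (0.155, with a median of -1.0). Without WOL control A the median was -1.56. EXPA15 differed by 2.22 between lines, which was not past the threshold (adjusted p = 0.163, limma). The other fixed lists were not called, with a smallest adjusted p of 0.432.

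The count of 29 changed with most single arrays. It was 134 without WOL control A, 0 without WOL control B, 1 and 0 without WOL BL 2 h A and B, 0, 6 and 0 without ATHB15 control 1, 2 and 3, 0 and 2 without ATHB15 BL 1 and 2, and 0, 16 and 15 with the UBQ, GAPDH and actin ratio as a covariate; the 29 differences kept their sign in each. Lower calls made up 72.4% of the 29, 92.3% of 13 with quantile normalization and 88.1% of 67 with median centring.

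The untreated lines were compared to see how provascular and stele cells differ before BL. The sorted line and any batch of that line cannot be told apart, so these differences are between lines and not surely between cell types. Class III peroxidase genes, whose products act in the cell wall, were among the transcripts furthest below WOL cells in ATHB15 cells: AT5G17820 at least 26.1-fold lower, AT3G01190 at least 24.9-fold, AT2G39040 at least 15.5-fold and AT1G30870 at least 15.04-fold, with AT5G66390 lower by -4.82 ± 0.79 on the log2 scale (SE, n = 3 and 2). AT5G40020, a thaumatin-like gene, was at least 23.1-fold lower (adjusted p = 5.36e-05, limma). The dirigent gene AT4G13580 differed by -5.30, AT1G30750 by -5.03, the invertase gene AT1G62660 by -4.46 and the lipid-transfer gene AT3G53980 by -4.40. Of these, AT4G13580 and AT1G62660 were called absent on 2 of 3 ATHB15 controls and AT5G66390 and AT1G30750 on 1, so their sizes are less certain. Single arrays moved most of these sizes: without WOL control A the limit was 10.6 for AT5G17820, 14.6 for AT3G01190, 9.01 for AT2G39040 and 5.55 for AT1G30870, and the log2 difference -4.03 for AT5G66390 and -3.64 for AT1G62660, and without WOL control B each was further below WOL cells. Without ATHB15 control 2 the log2 difference was -4.39 for AT4G13580, -4.37 for AT1G30750 and -3.39 for AT3G53980, and without ATHB15 control 1 it was -6.06 for AT4G13580 and -5.15 for AT3G53980. AT4G13580 ran from -6.34 to -4.35 over all alternatives. Higher in ATHB15 cells were 3xHMG-box2, which binds mitotic chromosomes, by 1.73, ZCF125, a kinesin, by 1.68, the thaumatin-like gene AT4G38660 by 1.81, AT5G25490 by 2.13, AT1G67720 by 1.87, AT3G15680 by 1.82 and AT1G73820 by 1.72 (1.10 without WOL control A and 2.34 without WOL control B). AT5G06440, AT1G52530 and the glutaredoxin gene ROXY2 were at least 2.74-fold, 2.85-fold and 2.94-fold higher, with ROXY2 called absent on 1 of 3 ATHB15 controls.

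XTH genes were lower in ATHB15 cells before BL, 6 of 6, with a median of -1.89 and an adjusted p of 0.00153 (limma), and adjusted p = 0.556 with an estimated correlation. XTH21 at -2.89 and XTH18 at -2.56 were called over all genes, and 4 members were lower adjusted over the list alone; XTH19 stood at -2.18. These 3 were called absent on 2 of 3 ATHB15 controls. Of the expansins 1 of 5 was called over all genes and 3 were lower adjusted over the list alone: EXPA8, at least 3.12-fold lower, was called, and EXPA18, with a signal at least 4.12-fold lower, and EXPA7 at -1.97, both known from root hairs, were not. That list was not called (0.207), nor were auxin response (0.114), procambium (0.881), ground tissue (0.881) or growth genes (0.987). GH3.1, at least 2.55-fold lower, and GSO1, a receptor of endodermal barrier formation, at -2.92 were called, and GUT2, a xylan synthesis gene of secondary walls, at -1.49 was not. EXPA7 and GSO1 were called absent on 2 of 3 ATHB15 controls and GUT2 on 1, and EXPA7, EXPA8, EXPA18 and GH3.1 on 1 of 2 WOL controls. Without WOL control A XTH18 stood at -1.73, XTH19 at -1.02, XTH21 at -2.34, EXPA7 at -1.18 and GSO1 at -2.20, and the limits were 1.70 for EXPA8 and 2.23 for EXPA18; without WOL control B each was larger, and XTH21 stood at -3.56 without ATHB15 control 1.

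The calls of these list members between the controls depended on single arrays and on the processing. Of the 21 or 22 alternatives run for each, the call changed in 6 for XTH18, 8 for XTH21, 8 for XTH19, 6 for EXPA8, 8 for GSO1, 14 for GH3.1, 2 for EXPA18, 1 for EXPA7 and 4 for GUT2. XTH18 and XTH21 were not called without WOL control A (0.253 and 0.209), ATHB15 control 2 (0.0579 and 0.0603) or ATHB15 control 3 (0.0583 and 0.0532), and XTH19 was called in 8 alternatives, with the smallest p (0.00552) without WOL control B and WOL BL 4 h A. XTH21 was not called with the GAPDH (0.0638), UBQ (0.0678) or actin ratio (0.187) as a covariate, with only the 2 groups (0.0729) or with an offset of 1 (0.0616), nor XTH18 with the actin ratio (0.0752) or offsets of 1 and 64 (0.0637 and 0.0565). EXPA8 and GSO1 were not called without WOL control A (0.245 and 0.315) or ATHB15 control 2 (0.0534 and 0.113). GH3.1 was not called without WOL control A (0.279), WOL control B (0.106) or ATHB15 control 1, 2 or 3 (0.0997, 0.0865 and 0.0880), nor with quantile normalization (0.116) or median centring (0.1).

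Limma called 663 probe sets between the controls, 611 lower and 52 higher, with 3531 at an unadjusted p under 0.05. The count was 28 without WOL control A, 223 without ATHB15 control 2, 342 without ATHB15 control 3, 550 without ATHB15 control 1 and 571 without WOL control B, and all 663 kept their sign. It was 338, 310 and 78 with the UBQ, GAPDH and actin ratio as a covariate, where the actin ratio was 28.4 to 48.3 in WOL control and 12.8 to 26.8 in ATHB15 control, and the UBQ ratio did not overlap either. Of the 80 probe sets called higher with BL in ATHB15 cells, 22 were also called lower between the controls, against 2.15 if independent. Both tests use the ATHB15 controls, with opposite sign, so these are not separate results. That sharing alone gave r = -0.40 across all genes in simulation, where the data gave -0.14. The median of all genes between the controls moved by 0.13 with quantile normalization and 0.27 with median centring, which left 84.7% and 77.6% of calls lower, against 92.2%. Of the 10 named rises, 10, 4, 5, 8 and 8 lost the call without WOL control A, WOL control B and ATHB15 control 1, 2 and 3, and of the 10 named falls 7, 1, 1, 2 and 1 did.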

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

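The tests of an exchanged label and of RNA quality for WOL control B, of the number of control arrays and with the UBQ and actin ratios were chosen after the result was seen. The probe sets whose 2 h BL change differed between the lines, by limma's test of the difference itself, numbered 29. The log2 change in ATHB15 cells minus that in WOL cells was 2.99 for AT3G06480, 2.9 for AT3G27150 and 2.84 for AT1G50380. It was -4.55 for AT1G62480, -3.73 for AT1G73780, -3.59 for AT3G59370, -3.55 for AT1G12080, -3.55 for AT4G11210, -3.43 for AT1G72230 and -3.03 for AT1G79620. The ATHB15 BL arrays were called absent for AT2G01300 (-4.56) and AT1G78260 (-3.15), so the change was lower by at least 4.56 and 3.15, and AT2G01300 stood at -3.89 without WOL control B. For EXLA2 (-4.12) 2 of 3 ATHB15 controls were absent as well, so its value gives a direction and no size. For AT2G43890 (4.48) and AT2G41810 (4.29) all arrays but ATHB15 BL were absent in this comparison. Their WOL change lies between 2 absent groups and is not measured, so their direction rests on the rise in ATHB15 cells. Of the 173 probe sets that fell in ATHB15 cells, 31 had the same sign in WOL cells at 2 h, 76 against WOL control A alone and 23 against WOL control B alone; of the 80 that rose, 33, 24 and 41 did.

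WOL control B lay between the other WOL arrays and the ATHB15 arrays, and the XTH calls in WOL cells were lost without it, as were the 29 calls for the difference between the lines, which were also lost without WOL BL 2 h B, ATHB15 control 1, ATHB15 control 3 or ATHB15 BL 1 and kept each sign. On an axis from the other 9 WOL arrays (0) to the ATHB15 controls (1) it stood at 0.419, below the ATHB15 controls at 0.802 to 1.04 (SD 0.118) and above the other WOL arrays at -0.182 to 0.250, which argues against an array that holds only ATHB15-sorted cells. Next to it among the WOL arrays stood WOL BL 4 h B at 0.250 and WOL BL 2 h B at 0.153. Plastid-encoded transcripts had a mean log2 value of 9.33 on WOL control B, near 9.18 in WOL control A and above 7.12 to 7.49 in the ATHB15 controls. Stronger 3' bias of its RNA stays open: over the other 9 WOL arrays the position correlated with the log2 GAPDH ratio at r = 0.425 (permutation p = 0.258) and rho = 0.417 (permutation p = 0.270), and at r = 0.0408 without the 2 arrays farthest from the median, too few arrays to decide. A mixture of sorted cells and a biological difference between plants were not tested.

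More BL calls were made in ATHB15 cells than in WOL cells at 2 h, 253 against 0 in limma, with 1505 at an unadjusted p under 0.05 in WOL. The additional control array is argued against as the whole cause, since with 2 arrays in each ATHB15 group, as in WOL, 67 to 160 were called. With the GAPDH or the actin ratio as a covariate 100% of the median size of the changes (1.99) and 63 and 96 calls remained. That median is of probe sets called without a covariate, and the count fell from 253 with each ratio. Whether 3' bias that these ratios track is the cause is left undecided. A difference in 3' bias between treated and control arrays stays open through the UBQ ratio, which separates BL arrays from controls: 91.7% of the median (1.82) but 1 call remained as the median SE rose from 0.375 to 0.505, so the median, which the test named in advance, does not decide it for this ratio. A difference between provascular and stele cells in the response to BL stays open as a hypothesis too, and the counts alone do not show that the lines differ.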

How the results depend on the processing

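Both deposited tables gave the same values for every result. The offsets, the detection filter, the GAPDH, UBQ and actin covariates and the omission of several arrays together were chosen after seeing the data. The cause was not tested unless the alternative itself gives it. In WOL cells, calls went from 0 to 1 at 0.5 h with an offset of 1, and from 0 to 1 at 1 h with median centring, an adjusted p under 0.1 or the detection filter. At 4 h they were 0 to 21 over single omitted arrays. From 1 to 2 h they were 1 with probe sets above the median mean, array weights or the detection filter, 3 with an intensity trend and 4 with an offset of 64. For ATHB15 BL, 253 calls became 608 with probe sets above the median mean, 542 with a trend, 75 with the replicate block, 47 with fits on the same line or the 2 groups, 587 at an adjusted p under 0.1, 103 with an offset of 1, 547 with the detection filter, 63, 1 and 96 with the GAPDH, UBQ and actin covariates, 381 without the WOL BL 4 h arrays, 495 without WOL control B and WOL BL 4 h A, and 20 to 160 over single omitted arrays. For the difference between lines, 29 became 13 with quantile normalization, 67 with centring, 194 with probe sets above the median mean, 70 without the lowest 25%, 145 with a trend, 79 with array weights, 0 with the block, 134 at an adjusted p under 0.1, 0 and 86 with offsets of 1 and 64, 123 with the detection filter, 16, 0 and 15 with these covariates, 80 without the WOL BL 4 h arrays, 0 without WOL control B and WOL BL 4 h A, and 0 to 134 over single omitted arrays. For the controls, 663 became 1053 at an adjusted p under 0.1, 274 and 310 with offsets of 1 and 64, 310, 338 and 78 with these covariates, 1064 without WOL control B and WOL BL 4 h A, and 28 to 571 over single omitted arrays; the replicate block could not be fitted. The 8 list calls became 0 with an estimated correlation, 13 with the actin covariate and 2 to 10 over single omitted arrays: 2 without WOL control B, 4 without WOL BL 1 h A and 5 without WOL BL 2 h A. The replicate labels paired arrays unevenly, with correlations of -0.192 to 0.417 in WOL, over 0.1 in 4 of 10 pairs, and 0.0103 in ATHB15. The correlation was 0.417 for WOL control with WOL BL 4 h and 0.203 with WOL BL 2 h, so these arrays may share a deviation by label. One named value reversed: EXPA18 at 0.5 h in WOL, 1.98, was -0.36 with the GAPDH covariate. Called named genes otherwise kept their sign in each alternative run. Signals near background limit folds, so bounds are given where all arrays of the lower group were called absent.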

Other observations

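Tests on the class III peroxidases, kinesins and ER body genes and with the UBQ and actin ratios were chosen after the comparisons were seen, and the other families were picked from gene names before any test. Transcripts encoded in the plastid genome were lower in untreated ATHB15 cells than in untreated WOL cells for 69 of 69 measured genes, with a median log2 difference of -1.90 and 41 called (adjusted p = 1.83e-47, limma camera; adjusted p = 0.705 with an estimated correlation). Mitochondria-encoded transcripts were lower for 15 of 16, median -1.33, with 4 called (adjusted p = 1.00e-08, and adjusted p = 0.705 with an estimated correlation). How evenly the labelling captures organelle transcripts was not tested, so the plastid and mitochondrial values describe array signals. After 2 h of BL in ATHB15 cells, 59 of 69 plastid-encoded transcripts were higher, median 0.46 (limma camera, adjusted p = 6.37e-07, and adjusted p = 0.749 with an estimated correlation). So were 15 of 16 mitochondrial ones, median 0.76 (adjusted p = 1.02e-04, and adjusted p = 0.705 with an estimated correlation). The ATHB15 controls enter both comparisons with opposite sign. Low values on them would add to the difference between lines and to the rise with BL, so the 2 results are not independent. The mitochondrial call was lost without ATHB15 BL 1 (0.0880), where the median was 0.28; it was 0.43 without ATHB15 control 1 and 1.16 without ATHB15 BL 2. The plastid median was 0.29 without ATHB15 BL 1, 0.70 without ATHB15 BL 2 and 0.98 with the UBQ ratio as a covariate. IAA genes, repressors of auxin response, were lower after BL in ATHB15 cells, 6 of 7, median -0.91 (adjusted p = 0.0141, and adjusted p = 0.705 with an estimated correlation). That call was lost without ATHB15 control 2 (0.0501) or ATHB15 BL 2. The mean log2 value of the family was 6.44, 6.92 and 6.80 in ATHB15 control 1, 2 and 3 and 6.35 and 5.87 in ATHB15 BL 1 and 2. The fall was thus smaller without ATHB15 BL 2. Tubulins were higher at 2 h in WOL cells, 5 of 5, median 0.60 (adjusted p = 0.00158; adjusted p = 0.705 with an estimated correlation). Of 210 family tests 34 were called with the preset correlation and 0 with an estimated one, where 14 had an unadjusted p under 0.05 in limma.

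Class III peroxidases were lower in untreated ATHB15 cells for 43 of 55 measured genes, with a median of -0.64 and 16 called (adjusted p = 5.65e-08, limma; adjusted p = 0.517 with an estimated correlation). The median was -0.33 with quantile normalization and -0.37 with median centring. Without the 8 genes that raised the question, 35 of 47 were lower and 8 called, with a median of -0.34 that fell to -0.12 with quantile normalization and -0.07 with median centring (adjusted p = 0.00115; adjusted p = 0.517 with an estimated correlation), and the call was lost without WOL control A (0.0777). Kinesins, motor proteins of microtubules, were higher for 34 of 42, median 0.45, with 3 called (adjusted p = 1.08e-05; adjusted p = 0.517 with an estimated correlation). Without the 3 that raised the question, 31 of 39 were higher and 0 called, with a median of 0.42 (adjusted p = 2.54e-04; adjusted p = 0.517 with an estimated correlation). The 2 medians were 0.72 and 0.69 with median centring, and 0.29 and 0.25 without WOL control A.

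ER body and lectin genes were among the largest rises after BL in ATHB15 cells, and further genes of this kind may rise too. In the 6 that had not raised the question the median log2 change was 0.834, with 4 higher and 2 lower. PYK10, an ER body glucosidase, differed by 1.86 and NAI1, a regulator of ER bodies called absent on 2 of 3 controls, by -0.88, and the signal was at least 2.93-fold higher for JAL33 and 3.32-fold higher for AT5G26280; JAL22 and JAL23 were called absent on all BL arrays. Over all genes 0 were called in limma, and adjusted over the list alone 3 were higher. The test was past the threshold at the preset correlation (adjusted p = 0.0252) but not with an estimated one (p = 0.108; adjusted p = 0.517 with an estimated correlation), so it leaves the hypothesis open. The call was also lost without ATHB15 control 2 (0.0542) or ATHB15 BL 1, and with the GAPDH ratio as a covariate (0.0748). The mean log2 value of the list was 5.78 to 6.08 in the ATHB15 controls, and 6.975 and 6.37 in ATHB15 BL 1 and 2. The rise was thus smaller without ATHB15 BL 1.

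ATHB15 controls had far more lower than higher calls against WOL control, 611 against 52. Scaling of every array to a common trimmed mean stays open: lower calls were 84.7% with quantile normalization and 77.6% with median centring, against 92.2%. A difference in 3' bias that the GAPDH ratio tracks is argued against as the whole cause of the excess of lower calls. With it as a covariate 95.5% of 310 calls were lower. Of the median difference of the lower calls 99.8% remained (-2.36 before and -2.35 after). That median is of probe sets picked without the covariate, so it bears on the question less than the share of lower calls. With the UBQ and actin ratios 105% and 99% remained, and 328 of 338 and 78 of 78 calls were lower. These 2 ratios did not overlap between the controls of the lines, so 3' bias that they track is not decided. The calls fell from 663 to 310, 338 and 78 as the median SE rose from 0.468 to 0.535, 0.546 and 0.593. A difference between the sorted cell types was not tested and stays open, and it cannot be told apart from any batch of a line.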
